A study of Homo sapiens with 4 samples.

How the data were processed

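RNA from cultured cells was hybridised to 4 one-colour (Cy3) Agilent gene expression arrays of 62976 spots, 1 array each for C4-2B with control hairpin, C4-2B with HIC1 hairpin, DU145 with control hairpin and DU145 with HIC1 hairpin. Groups came from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and labelled cRNA was made with a one-colour Quick Amp kit. The deposited files are scanner output and were not normalized between arrays. Per the file headers, the intensity values were made with Agilent Feature Extraction 10.7.1.1 (protocol GE1_107_Sep09) on a design file of build hg19, with local background subtracted and the signal detrended within each array, and with surrogate values for signals not above background. Any normalization between arrays that the authors used is not given in the sources used here. The deposited intensity columns used were the processed signal with its error and, for 1 alternative, the mean signal and the local background. The scanner software's flags for background, saturation and outlier spots were read as deposited.

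Control spots and spots with an outlier flag (between 193 and 349 per array) were left out. No spot was saturated. Log2 processed signals were reduced by the array's 75th percentile of them, and the spots of one probe were averaged. Of the 50599 probes, 902 had 10 spots each, and the median SD of log2 signal between such spots was between 0.051 and 0.063. Probe names were updated through a RefSeq gene table: 28170 probes matched by accession, 2621 by symbol and 620 by a unique synonym, and 19188 kept the file's name. This gave 36400 units, 21363 of them with a RefSeq symbol, which are called genes here. A gene was represented by its probe with the highest mean signal over the 4 arrays. It was measured in a line if that probe was well above background on both arrays. A gene with no probe above background on 1 of the 2 arrays was given as a bound, the brighter array's value against the higher of the gene's own value on the dim array and the lowest signal of any probe above background on that array. Such a bound leaves out the scanner error and rests on the dimmest probe above background, so every "at least" taken from it is nominal. The scanner software assumes a multiplicative error of 10% of the signal, and its error was propagated to each difference.

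The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Within a line, genes with an absolute log2 difference of at least 1 were counted. For each of 28 fixed gene lists, the median difference of the measured members was placed among the medians of 10000 random lists of the same size, drawn from protein-coding genes in 20 bins of mean expression. A list was said to stand apart below percentile 2.5 or above 97.5. Fibroblast markers, with fewer than 3 measured members, were not scored. Across the lines, limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment) was fitted to all 4 arrays with the line as a block, which leaves 1 residual degree of freedom. The line is the replicate there, with 2 pairs. Values of the 2 lines were also correlated across genes. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

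Named genes were HIC1, the 10 largest differences in each direction per line among genes with a symbol whose probes above background all lay on the same side, the 5 largest bounds in each direction per line, the 10 genes in each direction with the largest smaller difference among those past 2-fold in both lines, up to 4 members of each list with the largest difference in either line, all reported HIC1 targets, and CDH1, VIM, CDH2, FN1, ZEB1 and KLK3. Some genes that this rule takes are not reported here. Line markers were read on all arrays to check the labels.

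Alternatives were quantile and cyclic loess normalization, normexp background correction (offset 50) of the mean and background signals, centring on the median of probes above background on all arrays, looser filters on dim probes, the mean of a gene's probes, a 1.5-fold threshold, lists without genes of another list, and for limma an intensity trend, no line block, slide as a block in place of the line, and each array left out. Slide and line together with silencing leave no residual degree of freedom. The array labelled DU145 shctrl is the only one of its slide, so a slide block in place of the line leaves that array out, and the pair labelled C4-2B lies within 1 slide. Restricting counts to protein-coding genes and removing running-median trends on probe GC content and signal (25 bins, fitted on protein-coding genes) were added after seeing the data.

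The steps were tested on simulated data. For the across-line limma fit on 14739 genes, with 200 genes altered and the spread between lines as estimated from these arrays, 0% of 1.5-fold, 5.5% of 2-fold, 72% of 4-fold and 99.5% of 8-fold alterations were recovered, with 0, 10, 15 and 16 false calls beside 0, 11, 144 and 199 true ones. For lists of 25 genes in C4-2B (13882 genes), 93 of 100 lists shifted by 0.3 and 1 of 100 unshifted lists stood apart. In DU145 (13934 genes) these were 60 of 100 and 5 of 100. The simulated noise was independent between genes, so lists whose members vary together were not represented. For limma it was also independent between arrays, so a negative relation between the lines was not represented. Nothing was pooled. Units without a RefSeq symbol, 5823 measured in C4-2B and 5527 in DU145, were left out of the counts in the text.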

Results

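HIC1 encodes a zinc finger transcriptional repressor. Its silencing by lentiviral short hairpin RNA was examined in 2 human prostate cancer cell lines, C4-2B and DU145, each with its own control hairpin. C4-2B derives from LNCaP cells and is known for its expression of luminal prostate genes. DU145 is known to express few of them. Gene expression was measured on 4 one-colour microarrays, 1 array per group, labelled C4-2B shctrl, C4-2B shHIC1, DU145 shctrl and DU145 shHIC1. There was no replicate of any group, and the labels do not say whether the cultures were separate. Every difference within a line is the difference of 2 arrays, without a p-value. The error given after a difference is the scanner software's own signal error, propagated to the log2 difference. It covers the reading of the spots and not the variation between cultures, and the number of arrays limits the precision. Between 57.6% and 60.8% of the 50599 probes were well above background. The 75th percentile of the processed signal was 326.6 on the array labelled C4-2B shctrl, 394.2 on C4-2B shHIC1, 607.7 on DU145 shctrl and 472.0 on DU145 shHIC1. The array labelled DU145 shctrl came from a second slide and scan, and the 3 others shared the first slide.

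The target gene was read first. HIC1 was represented by 1 probe, A_23_P129856, at chromosome 17, 1962633 to 1962692 on hg19, the build of the array's design file. Its place in an exon or untranslated region was not analysed here. HIC1 was dim but well above background on all 4 arrays, at log2 -3.29, -3.20, -2.91 and -3.24 relative to the 75th percentile in the order C4-2B shctrl, C4-2B shHIC1, DU145 shctrl, DU145 shHIC1. The array labelled C4-2B shHIC1 was 0.08 ± 0.27 (log2, scanner error) above its control, so HIC1 was not lower there. The array labelled DU145 shHIC1 differed from its control by -0.33 ± 0.25. With normexp background correction the differences were -0.08 in C4-2B and 0.01 in DU145. The DU145 difference was -0.68 with cyclic loess and -0.52 with quantile normalization, so its size depended on the processing. Of these settings, normexp alone changed its sign, and it changed the sign in C4-2B as well. Normexp adds an offset of 50 to each signal, which draws differences of dim probes such as that of HIC1 towards 0. The cause of the sign changes was not tested. The groups are called below by their labels alone.

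The control arrays were compared for genes that distinguish the lines. KLK3, which encodes prostate-specific antigen, stood at log2 -3.09 on the array labelled C4-2B shctrl and -3.21 on DU145 shctrl. KLK2 stood at -1.42 and -1.41, and TMPRSS2, an androgen-regulated serine protease, at -1.82 and -1.22. Of the 12 luminal genes on the list, 2 were at least 2-fold higher on the array labelled C4-2B shctrl than on DU145 shctrl and above background there. HOXB13, a prostate homeobox gene, stood at percentiles 65.8 and 55.2 of genes on the arrays labelled C4-2B and was not well above background on those labelled DU145. FOLH1, which encodes prostate-specific membrane antigen, was dim on the array labelled C4-2B shctrl (-4.35) and not well above background on the 3 others. The median difference of the 12 luminal genes, DU145 shctrl minus C4-2B shctrl, was -0.25, and -0.21 between the shHIC1 arrays, which shared a slide. All 13 genes expected in DU145 and not in LNCaP derivatives were above background on all 4 arrays. Their median difference was -0.52 between the control arrays, with 5 of 13 higher in DU145, and 0.10 between the shHIC1 arrays, with 8 of 13 higher. GSTP1, a glutathione transferase silenced in LNCaP cells, was at 8.74 on the array labelled C4-2B shctrl and 7.40 on DU145 shctrl. The intermediate filament gene VIM was at 8.17 and 7.24. ANXA1, an annexin, and AXL, a receptor tyrosine kinase, were lower on DU145 shctrl than on C4-2B shctrl by log2 differences of -3.64 and -5.78. Within the first slide, the array labelled DU145 shHIC1 differed from C4-2B shHIC1 by -6.37 in ANXA1 and by -4.80 in AXL. Other genes of this list were higher on the arrays labelled DU145. The urokinase gene PLAU differed by 2.42 between the control arrays and 3.20 between the shHIC1 arrays, the caveolin genes CAV1 by 2.05 and 0.37 and CAV2 by 2.00 and 0.74, and EGFR by 0.76 and 0.56. The median percentile of the 13 genes among all genes was 93.7 on C4-2B shctrl and 94.5 on DU145 shctrl. The levels of most luminal genes and of the 13 genes expected in DU145 go against the label of the C4-2B arrays. The luminal gene SLC45A3 stood at 1.0 and -0.07 on the arrays labelled C4-2B (shctrl, shHIC1) and 1.32 and 1.57 on those labelled DU145. Its levels and the low AXL and ANXA1 go against the label of the DU145 arrays, while PLAU, CAV1, CAV2 and EGFR do not. Every direction given for either line is that of arrays so labelled.

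**Figure D1:**
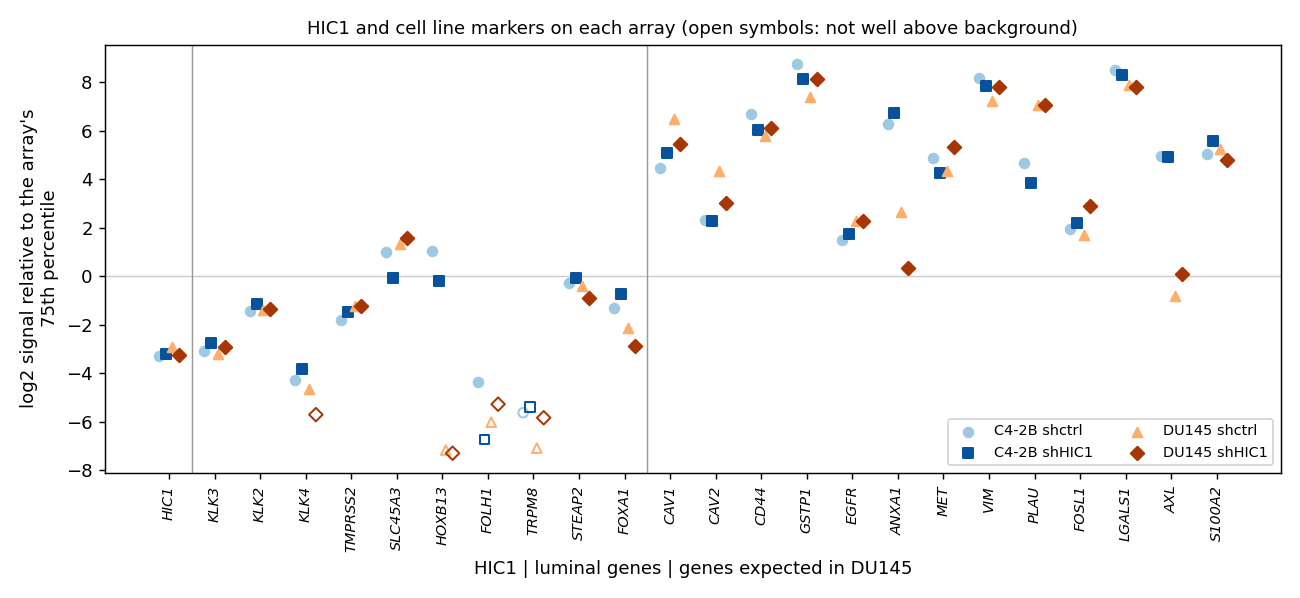
Log2 signal relative to the array's 75th percentile (vertical axis) of HIC1, 10 luminal genes and 13 genes expected in DU145 (horizontal axis), 1 symbol per array, open where the gene was not well above background. HOXB13 is open on the arrays labelled DU145, and HIC1 lies between -3.29 and -2.91 on all of them.

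In the pair labelled C4-2B, inflammatory genes were lower on the shHIC1 array. Of 24 measured genes induced by NF-kB signalling, 12 were at least 2-fold lower and 1 was at least 2-fold higher, with a median log2 difference of -0.96 (percentile 0.0 among 10000 random lists matched on expression). EBI3, a cytokine subunit, differed by -2.67 ± 0.20, LTB (lymphotoxin beta) by -2.09 ± 0.21 and TNFAIP2 by -1.70 ± 0.20. Of 24 measured chemokines, cytokines and their receptors, 9 were at least 2-fold lower and 1 higher, with a median of -0.74 (percentile 0.0). IL11 differed by -2.23 ± 0.24, IL32 by -2.01 ± 0.22 (another probe -0.35) and CXCL8, a neutrophil chemoattractant, by -1.67 ± 0.21 (another probe -0.43), while CXCL3 differed by 0.31 ± 0.21. Of 29 interferon-stimulated genes, 5 were at least 2-fold lower and 0 higher, with a median of -0.45 (percentile 0.0). The antiviral GTPase gene MX1 differed by -3.33 ± 0.34, IFIT3 by -1.37 ± 0.29 and SAMD9L by -1.43 ± 0.30.

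Mesenchymal genes, and genes of proteases and their inhibitors, were lower as lists in the same pair. Of 25 measured mesenchymal genes, 6 were at least 2-fold lower and 1 higher, with a median of -0.34 (percentile 0.1). The collagen VI genes COL6A2 and COL6A1 differed by -3.19 ± 0.28 and -1.74 ± 0.21, and the lysyl oxidase gene LOXL2 by -1.12 ± 0.20, while the collagen gene COL5A1 differed by 1.12 ± 0.25. With the mean of a gene's probes in place of the brightest, the mesenchymal median was -0.16, at percentile 5.53. VIM differed by -0.34 ± 0.20, ZEB1, a repressor of epithelial genes, by -0.35 ± 0.20 and the N-cadherin gene CDH2 by 0.58 ± 0.20. The E-cadherin gene CDH1 and the fibronectin gene FN1 were not well above background on either array. Of 27 measured protease and inhibitor genes, 7 were at least 2-fold lower and 1 higher, with a median of -0.35 (percentile 0.14). The interstitial collagenase gene MMP1 differed by -2.31 ± 0.20, ADAMTS1 by -2.04 ± 0.24, the metalloprotease inhibitor gene TIMP2 by -1.79 ± 0.20 and the tissue plasminogen activator gene PLAT by -1.71 ± 0.22. Hypoxia and glycolysis genes had a median of -0.33 over 25 members, 2 of which were at least 2-fold lower (percentile 0.0). NDRG1 differed by -1.53 ± 0.20 and ANKRD37 by -1.43 ± 0.20. Immediate early genes had a median of -0.27 over 25 members (percentile 0.24), with ATF3, a stress-induced transcription factor, at -1.29 ± 0.20 (its 4 probes from -2.13 to 0.20) and KLF4, a Krüppel-like factor, at 1.69 ± 0.23.

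The largest single differences of that pair lay outside these lists. The largest differences downward were in DCDC2, a doublecortin domain gene (-4.20 ± 0.23), the growth factor gene IGF2 (-3.96 ± 0.21), CCDC3 (-3.84 ± 0.22), PREX1, a Rac exchange factor (-3.66 ± 0.21), GPRC5C (-3.62 ± 0.20), BASP1 (-3.50 ± 0.20) and the organic anion transporter gene SLCO2B1 (-3.47 ± 0.23). ARHGDIB, which encodes a GDP dissociation inhibitor, differed by -3.44 ± 0.21, GSE1 by -3.43 ± 0.25 and FAM110C by -3.41 ± 0.22. The largest differences upward were in CEP68, a centrosomal protein gene (3.95 ± 0.22, another probe 0.38), GRHL3, an epithelial grainyhead transcription factor (3.90 ± 0.25), IQCH-AS1 (3.84 ± 0.22), the microRNA host transcript MIR155HG (2.90 ± 0.24), MYO3A (2.87 ± 0.28) and PCDHGC4 (2.72 ± 0.32). KRTAP10-2 and SLC17A3 differed by 2.56 and 2.47. Some genes were well above background on 1 array of the pair only and have a bound. HTRA1, a secreted serine protease, was at least 31.7-fold lower on the shHIC1 array. The tubulin gene TUBB2B was at least 28-fold lower, the Wnt receptor gene ROR2 at least 25.4-fold, the hepatic lipase gene LIPC at least 22.1-fold and SEL1L3 at least 18-fold lower. In the other direction LDHAL6B was at least 40.8-fold higher, CXorf51A 26.1-fold, PCDHA12 22.5-fold, PRICKLE1 20.1-fold and ZNF491 15.3-fold, each as a nominal lower bound. The bounds leave out the scanner error, which was 1.45 for the log2 difference of LDHAL6B.

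Counted over all genes with a RefSeq symbol, 1135 of 15474 measured in the pair labelled C4-2B (7.3%) differed at least 2-fold, 305 higher and 830 lower on the shHIC1 array. Scanner error alone, simulated on unchanged genes of this pair, put 9 of 15474 past that threshold. With normexp background correction the count was 479. Of 215 such genes with at least 2 probes above background, 160 (74.4%) had all probes on the same side. Were the members of a list to vary independently, 1.4 of 27 scored lists would be expected to stand apart. Genes of a list can vary together and lists share genes, so this is not a chance rate for these lists. In total 7 of the 27 stood apart from random lists. The other lists did not, among them epithelial genes (median -0.07, 5 of 24 lower and 2 higher, with DSP at -1.55 and CLDN4 at 1.44, and another probe of each at -0.86 and 0.14), integrins (0.06), Eph receptors and ephrins (0.07, EFNB3 at -1.35), androgen targets (0.13, NNMT at -1.58 and MAF at -1.39), p53 targets (0.11, SESN1 at 1.71), mitosis (0.17), replication (0.12), cholesterol synthesis (0.01, DHCR7 at 1.68), Wnt targets (0.04, NKD2 at -2.46) and ribosomal proteins (0.00). Nor did the unfolded protein and amino acid response (-0.07), heat shock (-0.04), oxidative phosphorylation (0.03), histones (0.09), neuroendocrine (0.25), luminal (0.29), DU145 marker (-0.06), leukocyte (0.13) or cancer-testis genes (-0.36). Of fibroblast markers, 2 were measured in each pair and not scored.

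In the pair labelled DU145, ribosomal RNA, small nucleolar RNA and histone genes were higher on the shHIC1 array. The ribosomal RNA genes RNA5-8SN5, RNA28SN5 and RNA18SN5 differed by 7.64 ± 0.28, 5.10 ± 0.20 and 4.65 ± 0.20. SNORD26 differed by 4.87 ± 0.21, SNORA16B by 4.54 ± 0.29, SNORD3B-1 by 4.45 ± 0.20, SNORA16A by 3.92 ± 0.20 and the histone gene H2AC11 by 4.31 ± 0.22. HAPLN2, a hyaluronan link protein gene, and SFTA1P differed by 5.68 ± 0.23 and 4.90 ± 0.20, with another SFTA1P probe at 0.13 and another SNORA16B probe at 0.90. Over 217 measured genes of RNA classes without a poly(A) tail, the median difference was 0.85, and 91 were at least 2-fold higher against 0 lower. Of 17 measured histone genes, 6 were at least 2-fold higher and 2 lower (median 0.57, above all 10000 random lists). H3C10 differed by 2.81 ± 0.20 (another probe 0.53) and H4C8 by 2.58 ± 0.20. All 42 ribosomal protein genes were higher and 8 at least 2-fold (median 0.71, above all 10000 random lists), with RPL14 at 1.47 ± 0.20. With quantile normalization that list's median was 0.01, at percentile 87.19. The control array of this pair, alone on its slide, was the one that stood apart in these classes. Of 267 such genes above background on at least 1 array, 219 were so on this one and between 254 and 262 on the others. Its median over the 267 lay at log2 -1.98, against -0.16, -0.83 and -0.98 on the arrays labelled C4-2B shctrl, C4-2B shHIC1 and DU145 shHIC1. Its spike-in signal was 624.6, against 2814.6, 1945.0 and 2276.6. For DU145, slide and group cannot be told apart.

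**Figure D2:**
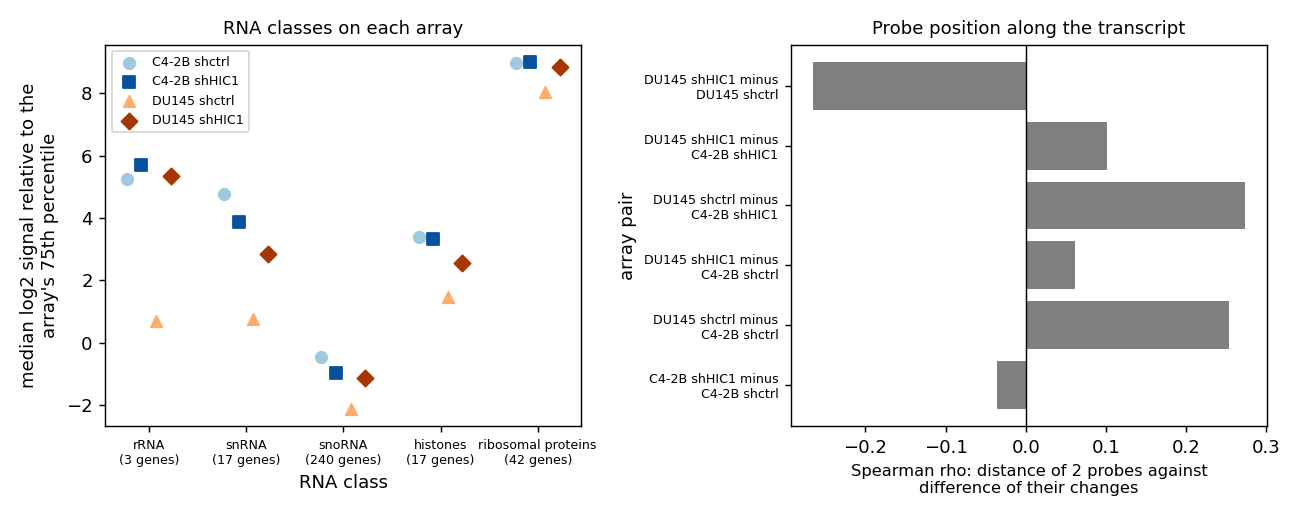
Left, median log2 signal relative to the array's 75th percentile (vertical axis) of 5 RNA classes (horizontal axis), 1 symbol per array. Right, Spearman's rho across transcripts with 2 probes (horizontal axis) between the distance of the probes and the difference of their changes (probe nearer the 3' end minus the other), for each pair of arrays (vertical axis). The array labelled DU145 shctrl is the lowest in all 5 classes, and its 3 pairs have rho of 0.254, 0.274 and -0.266.

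Mitotic genes were lower as a list on the array labelled DU145 shHIC1. The median over 35 genes was -0.41 (percentile 0.03), and 3 were at least 2-fold lower. These were CENPE, a centromere motor (-1.08 ± 0.20), CDC25C, the phosphatase that activates the mitotic kinase (-1.04 ± 0.20), and CCNA2, cyclin A (-1.01 ± 0.20), while the probes of the proliferation marker MKI67 went both ways (-0.54 to 1.5). Epithelial genes had a median of -0.34 over 25 members (percentile 1.61), but none was at least 2-fold lower and 2 were higher, ST14 at 1.27 ± 0.24 among them. Under quantile normalization the epithelial percentile was 5.73, and with the mean of probes it was 16.25. CDH1 was well above background on the control array alone and at least 3.5-fold lower on the shHIC1 array. VIM differed by 0.57 ± 0.20, CDH2 by 0.64 ± 0.22 and ZEB1 by -0.37 ± 0.20, with another ZEB1 probe at 0.43. Cancer-testis genes stood above random lists with 6 measured members (median 0.48, percentile 98.33), led by MAGEA6 at 2.26 ± 0.23 and SSX2 at 1.18 ± 0.27. Their median was 0.02 when genes above background on 1 array were admitted.

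The largest differences downward of the pair labelled DU145 were in FLJ13224 (-3.37 ± 0.32), the gap junction gene GJA1 (-3.28 ± 0.30), SVIP (-3.07 ± 0.23), RFPL3S (-2.75 ± 0.23), RNASE4, a secreted ribonuclease (-2.73 ± 0.21), and SLIT2, a secreted guidance ligand (-2.71 ± 0.28). DEFB121, the orphan nuclear receptor gene ESRRG, FRMD4B and PCDHB6 differed by -2.64, -2.46, -2.38 and -2.37. Among genes with a bound, FAM87B was at least 46.8-fold lower on the shHIC1 array, ECSCR 41.6-fold, SENCR 38.0-fold, TP53TG3C 37.3-fold and the alarmin gene IL33 30.6-fold. H2BC1 was at least 44.4-fold higher, PODN 33.3-fold, C3AR1 28-fold, PHACTR2-AS1 24.4-fold and CD86 19.0-fold. Among members of other lists, the chemokine gene CXCL3 differed by -2.06 ± 0.22, the p53 target CCNG1 by -1.90 ± 0.20 (another probe -0.68), the clamp loader gene RFC3 by -1.88 ± 0.20, DHCR7 by -1.89 ± 0.20, ANXA1 by -2.30 ± 0.20, MMP1 by 1.41 ± 0.20 and the integrin gene ITGB3 by 1.43 ± 0.30. The lists that stood apart in C4-2B did not do so here in the main analysis. NF-kB genes had a median of -0.29 with 4 of 24 lower and 0 higher (percentile 6.36), chemokines and cytokines -0.29 with 5 of 24 lower and 0 higher (percentile 8.85), interferon-stimulated genes -0.16 (percentile 39.67) and mesenchymal genes -0.30 (percentile 2.79, and 1.97, which stands apart, when genes above background on 1 array were admitted). Nor did proteases (-0.06), hypoxia and glycolysis (-0.27), immediate early genes (-0.21), integrins (-0.12), Eph receptors and ephrins (0.01), androgen targets (-0.24), p53 targets (-0.23), replication (-0.13) or Wnt targets (-0.33, but at percentile 0.6 with no filter on dim probes). The unfolded protein and amino acid response (0.03), heat shock (-0.13), oxidative phosphorylation (0.22), neuroendocrine (0.10), luminal (-0.02), DU145 marker (0.03) and leukocyte genes (0.09) did not stand apart either. The difference between the lines in these lists was not tested.

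Counted over all genes with a RefSeq symbol, 1671 of 15449 measured in the pair labelled DU145 (10.8%) differed at least 2-fold, 857 higher and 814 lower. Of the genes past the threshold, 51.3% were higher, 39.9% with cyclic loess normalization and 68.4% after trends on probe GC content and signal were removed. Among protein-coding genes 619 were higher and 775 lower, and among the other RefSeq genes 238 were higher and 39 lower. With normexp the total was 1061. No count for this line can be made without the array labelled DU145 shctrl. Of 436 genes past the threshold with at least 2 probes above background, 238 (54.6%) had all probes on the same side, against 74.4% in C4-2B. The share that probes of unrelated direction would give was not computed. The 54.6% is therefore not read as support for the direction of these calls. In total 5 of 27 scored lists stood apart, where 1.4 would be expected if list members varied independently, which they need not do.

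**Figure D3:**
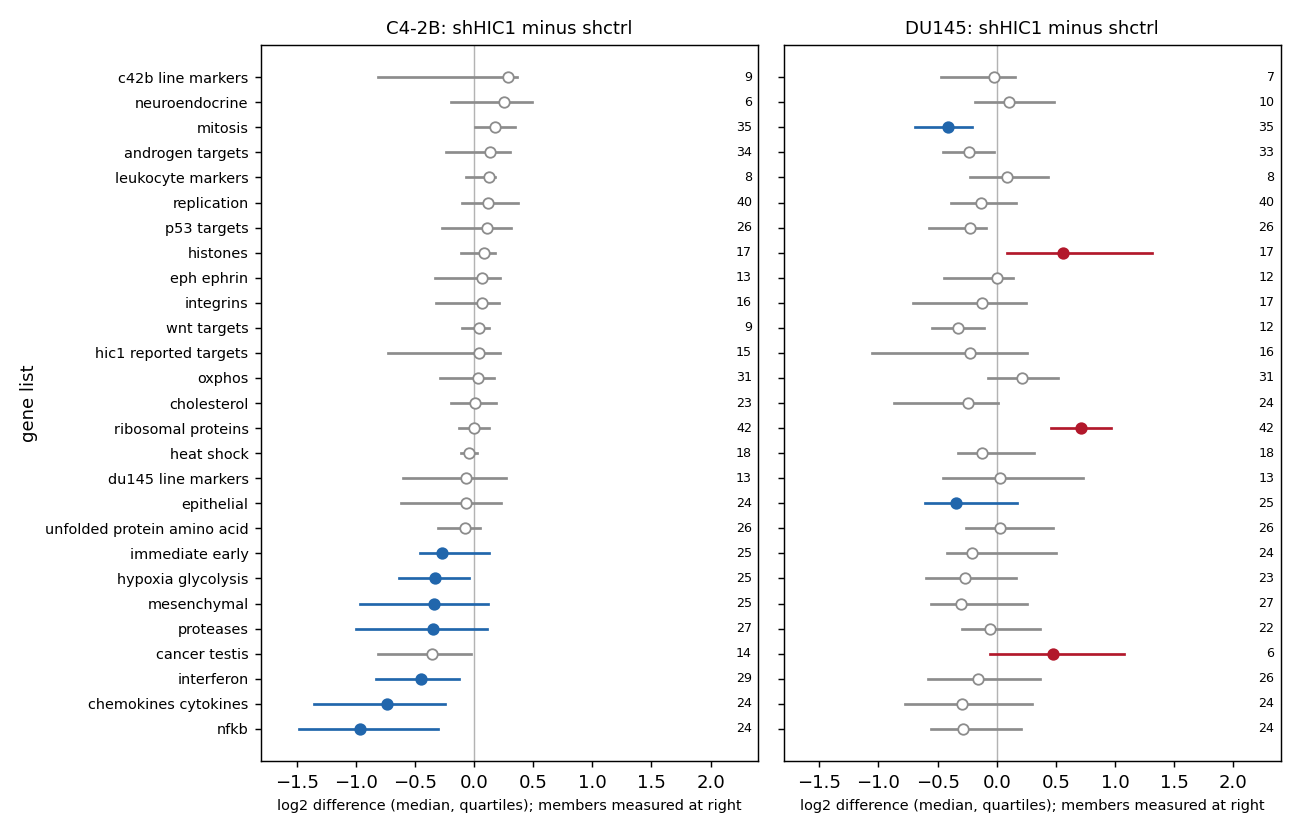
Median log2 difference, shHIC1 minus shctrl (horizontal axis), of each fixed gene list (vertical axis) in the pairs labelled C4-2B and DU145, with quartiles as lines and the number of measured members at the right. Filled symbols stand outside the central 95% of random lists, below in blue and above in red. NF-kB genes lie at -0.96 in C4-2B and -0.29 in DU145, and ribosomal proteins at 0.00 and 0.71.

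Genes reported in the literature as bound or repressed by HIC1 did not stand apart as a list in either line in the main analysis. With no filter on dim probes their C4-2B median was -0.33, at percentile 0.68, which stands apart below. In C4-2B 2 of 15 measured were at least 2-fold higher and 3 lower (median 0.04, percentile 51.02), and in DU145 0 of 16 were higher and 5 lower (median -0.23, percentile 39.67). FGFBP1, a carrier of fibroblast growth factors, differed by 1.84 ± 0.24 in C4-2B and 0.15 ± 0.38 in DU145. The chemokine receptor gene CXCR4 was lower in both pairs, by -1.49 ± 0.24 and -1.22 ± 0.21, and the ephrin gene EFNA1 differed by -1.15 ± 0.20 and -0.93 ± 0.20. The cell cycle inhibitor gene CDKN1C differed by -3.15 ± 0.21 and -0.04 ± 0.20. The deacetylase gene SIRT1 differed by 0.44 ± 0.20 and -1.58 ± 0.20, and the transcription factor gene SOX9 by 0.09 ± 0.21 and -1.84 ± 0.20. EPHA2 differed by 0.08 and 0.91, CDKN1A by -0.45 and 0.85, CCND1 by 0.04 and -0.41, IL6 by -0.52 and -1.0, VLDLR by -0.21 and -0.69, LRP8 by 0.12 and 0.57, PTCH1 by -0.93 (another probe 0.30) and 0.12, and TIAM1 by 0.31 and 0.06. LCN2 was at least 2.4-fold lower in C4-2B and differed by -2.29 ± 0.30 in DU145. SNAI2 was at least 2.4-fold lower in DU145 and not well above background in C4-2B. ATOH1, ACKR3 and SCN3B were not well above background on any array.

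The 2 lines were then compared. Across 14739 genes above background on all 4 arrays, the differences of the lines were negatively related, with Pearson's r of -0.203 and Spearman's rho of -0.231. Genes are not independent replicates, so no p-value is given. The 2 differences share no array. At least 2-fold lower in both pairs were 33 genes, against 37.8 expected for independent lists, and 12 were higher in both, against 15.3 expected. In opposite directions, 47 were higher in C4-2B and lower in DU145 against 13.8 expected, and 93 were lower in C4-2B and higher in DU145 against 41.9. With normexp 7 genes were lower in both, 1 was higher in both and 66 differed in opposite directions. With no filter on dim probes these counts were 158, 102 and 495. Among the genes lower in both were MARCKS, a protein kinase C substrate (-3.41 ± 0.20 and -1.58 ± 0.20), the lymphocyte activation antigen gene CD69 (-3.28 ± 0.32 and -1.51 ± 0.26), SHISA3 (-1.54 and -2.34), CCL2, a monocyte chemoattractant (-1.32 and -1.50), the basement membrane collagen gene COL4A1 (-1.31 and -1.31), the small GTPase gene RHOB (-1.30 and -1.23), CYP1A1 (-1.78 and -1.31), the mucin gene MUC5AC (-1.67 and -1.28), CSGALNACT1 (-1.71 and -1.42) and ARGFX (-1.36 and -1.41). Among those higher in both were the scavenger receptor gene MARCO (1.45 and 1.58), ICMT, a methyltransferase of prenylated proteins (1.71 and 1.43), LRRD1 (1.28 and 2.31), MIR124-1HG (1.27 and 1.81), SPATA21 (1.30 and 1.23), the RNA editing family gene ADARB2 (2.08 and 1.17), SLC6A17 (1.53 and 1.15), SNORD105 (1.15 and 1.30), CISH, a suppressor of cytokine signalling (1.1 and 1.24), and YPEL4 (1.09 and 1.42). With the mean of probes, the DU145 differences of LRRD1 and CSGALNACT1 were -0.96 and 0.00. Another probe lay on the other side of 0 for LRRD1 in C4-2B (-0.81), and in DU145 for CSGALNACT1 (1.42, past 2-fold), SPATA21 (-0.37) and MUC5AC (0.08). Another probe lay under 2-fold on the same side for ICMT (0.18), SPATA21 (0.06) and MUC5AC (-0.18) in C4-2B and for LRRD1 (0.52), ICMT (0.97) and RHOB (-0.59) in DU145.

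A limma fit with the cell line as a block asked whether the mean difference was large against the disagreement of the 2 lines. With 1 residual and 12.84 prior degrees of freedom, each gene's SE rested mostly on a spread pooled over all genes. It is not a measure of that gene's own disagreement. At a Benjamini-Hochberg adjusted p of 0.05 it called 0 of 14739 genes, and 425 had an unadjusted p under 0.05, which is 2.9% of the genes tested. That share is below the threshold of 0.05 itself. The differences of the lines were negatively related (covariance -0.0754), which raises their disagreement against their mean. The fit was therefore conservative here, and its 0 calls partly restate that relation. The smallest adjusted p in that limma fit was 1. With normexp background correction limma called 16 genes, 13 higher and 3 lower. MARCKS had a mean log2 difference of -2.50 ± 0.47 (SE) and CD69 of -2.39 ± 0.46, both with a limma adjusted p of 1. Adjusted over the list alone, CCL2 and CXCR4 passed among 22 tested chemokines, cytokines and receptors (smallest adjusted p 0.048 in limma), and NKD2, a Wnt antagonist, among 9 tested Wnt targets (0.0431), though another NKD2 probe was at 0.19 in DU145. No member of the other lists passed, adjusted over the list alone, and no list member passed over all genes. CXCR4 did not pass among 15 tested reported HIC1 targets, where the smallest adjusted p in limma was 0.0654. Each of the 28 lists was adjusted on its own, with no adjustment across lists, so a member can pass in some lists by chance.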

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

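The tests of the slide, of measured genes alone, of HIC1 silencing in the other line, of the line markers and of protein-coding genes were chosen after their results had been seen; those of GC content and of probe position were written before. Of the named genes measured in both pairs, 10 differed at least 2-fold in opposite directions in the 2 lines, a difference that was not tested, and no list stood apart in opposite directions. In the order C4-2B, DU145, the log2 differences between the shHIC1 and shctrl arrays were 3.95 and -1.31 for CEP68 (another probe 0.38 and -0.60), -3.66 and 1.04 for PREX1, -3.62 and 2.32 for GPRC5C, -2.31 and 1.41 for MMP1, 1.71 and -1.09 for SESN1, and 1.68 and -1.89 for DHCR7. For RNA species they were -1.89 and 7.64 for RNA5-8SN5, -2.28 and 4.87 for SNORD26, -1.20 and 4.54 for SNORA16B, and -1.10 and 3.92 for SNORA16A.

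RNAs without a poly(A) tail were higher on the array labelled DU145 shHIC1 than on its control. Were probe GC content the source, the median would fall under 0.5 once its trend was removed. A median above 1 was set to argue against it. Over 267 genes, dim probes included, it was 1.07 (95% bootstrap interval over genes 0.95 to 1.30), against 0.99 before. This argues against GC content as the whole source for these genes, though the interval reached below 1. Over the 217 measured ones it was 0.95 (0.76 to 1.06) against 0.85, between those limits, so the rule does not decide there. In both sets the median did not fall, and both intervals lay above 0.5. A batch of labelling or hybridisation could account for the pattern, since the array on the second slide lay below the mean of the 3 others, the other line included, by a median of -1.37 (-1.60 to -1.16) over the 267, dim probes included, and of -1.15 (-1.33 to -0.88) over 215 measured on all 4 arrays. Over 3261 transcripts with 2 probes, the change of the probe nearer the 3' end minus that of the other also fell with the distance between them in DU145 (Spearman's rho -0.266, and -0.036 in C4-2B; median -0.255), so that 3' probes were relatively brighter on the control array. Both values are consistent with the control array's RNA having been primed or degraded differently, and a response of DU145 cells to HIC1 silencing cannot be told apart from the slide, although the same RNAs had a median of -0.35 (-0.44 to -0.27) in C4-2B, and -0.34 over the 251 measured there.

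Most luminal genes that distinguish C4-2B were near their DU145 level on the arrays labelled C4-2B. RNA of a cell line without luminal expression on those arrays is a candidate explanation, since 13 of 13 genes expected in DU145 and not in LNCaP derivatives were above background on the C4-2B control array. By that measure 10 of 12 luminal genes were also present there, and 8 of 12 on DU145 shctrl, so presence alone separates the lines poorly. The median percentile among genes was 93.7 and 94.5 on these 2 arrays for the 13 genes, and 44.2 and 38.0 for the luminal genes. HOXB13 goes against RNA of DU145 on those arrays, at percentiles 65.8 and 55.2 of genes there and not above background on either array labelled DU145. Loss of luminal expression within C4-2B stays open and untested. Each array correlated best across genes with the other array of its line, at r of 0.981 for C4-2B and 0.973 for DU145. These values go against an exchange of single arrays between the lines. Any other mix of the labels stays open and untested.

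The lines differed in opposite directions more often than independent lists would give. A trend on probe GC content and signal is argued against, because r across genes was -0.211 after both trends were removed and -0.203 before. Non-coding RNAs are argued against as the whole source, because r was -0.186 over 13315 protein-coding genes. A different response of the 2 lines, and the separate slide of the DU145 control, may each contribute and were not separated. The arrays of the C4-2B pair also differed in RNAs without a poly(A) tail, with 42 of 251 measured at least 2-fold lower and 1 higher. Their spike-in signal was 2814.6 on shctrl and 1945.0 on shHIC1, against 624.6 and 2276.6 in DU145. Whether such differences between the arrays of each pair contribute to r was not tested.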

How the results depend on the processing

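The protein-coding counts and the removal of GC and signal trends were chosen after seeing the data. HIC1 differed by -0.079 in C4-2B and 0.013 in DU145 with normexp, and by -0.677 in DU145 with cyclic loess. The offset of 50 in normexp draws differences of dim probes towards 0. What changed the signs was not tested, and neither were other causes. The 2-fold counts in C4-2B and DU145 became 479 and 1061 with normexp, 2860 and 3425 with no filter on dim probes, and 3137 and 4919 at 1.5-fold, a lower threshold. The C4-2B count became 1884 with genes above background on 1 array. The r between the lines was -0.137 with that filter and -0.126 with no filter. In limma 16 genes passed with normexp, where the estimated prior degrees of freedom were infinite, 0 under every other alternative, and from 0 to 0 when each array was left out (the line block was dropped there as well, since 3 arrays leave it no residual degree of freedom, and 1 array alone in its arm is assumed to vary like the others); with slide as a block in place of the line it was 0. No paired analysis beyond the line block was possible because each group had 1 array. In DU145, 3 lists stood apart with quantile normalization and 3 with GC and signal trends removed, against 5. The cancer-testis median in DU145 was -0.046 with no filter. With the mean of probes LRRD1 in DU145 was at -0.96 and CSGALNACT1 at 0.00. Beyond those in the report, lists that stood apart under an alternative alone were epithelial genes in C4-2B with no filter (percentile 2.41), cholesterol genes in DU145 with normexp (2.43), and luminal genes in C4-2B and DU145 markers in DU145 with the mean of probes (98.32 and 98.74). In C4-2B the NF-kB, chemokine, interferon, protease, hypoxia and immediate early lists stood apart under every alternative, and in DU145 mitosis and histones did. After removal of both trends 68.4% of DU145 genes past 2-fold were higher, against 51.3%. The causes were not tested. Of the named genes past 2-fold, normexp took 24 of 84 in C4-2B and 30 of 97 in DU145 under the threshold. Signal over background limits HIC1 itself, whose probe lay between percentiles 32.6 and 36.5 of genes.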

Other observations

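In the pair labelled DU145 several cholesterol synthesis genes lay lower on the shHIC1 array, with 3 of 24 measured at least 2-fold lower and 0 higher (median -0.24, percentile 8.99, which does not stand apart, and 2.43, which does, with normexp background correction). DHCR7 differed by -1.89, HMGCS1 by -1.15, SC5D by -1.09 and INSIG1 by -0.93. In the pair labelled C4-2B, epithelial genes went both ways, with CLDN4, a tight junction gene, at 1.44 and the desmosomal genes DSP and PKP3 at -1.55 and -1.32. Of 24 measured, 5 were at least 2-fold lower and 2 higher. Among those above background on 1 array only, 4 had a bound at least 2-fold lower and 0 higher. The replication gene MCM5 differed by 0.95 in C4-2B and -1.13 in DU145, where another probe was at -0.55.

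The lines differed by more genes between the control arrays, which lay on 2 slides, than between the shHIC1 arrays, which shared 1 slide. At least 2-fold differences numbered 2462 higher and 1920 lower in DU145 between the control arrays, and 1353 and 1160 between the shHIC1 arrays, of 14739 genes. The array labelled DU145 shHIC1 correlated with C4-2B shctrl at r = 0.958 across genes, and the array labelled DU145 shctrl at 0.925. With C4-2B shHIC1 these values were 0.945 and 0.923. The 2 arrays of a line correlated more closely, at 0.981 for C4-2B and 0.973 for DU145.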
